A study of Xenopus tropicalis with 35 samples.

How the data were processed

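Chromatin accessibility was measured by ATAC-seq in 35 libraries of Xenopus tropicalis tadpole tail tissue, 18 in an experiment with trichostatin A (TSA, 20 nM) and 17 in an experiment with 3-deazaneplanocin (DZNep, 15 µM). Each had its own vehicle, named as DMSO in the sample names of the TSA experiment. Groups were taken from the labels, which give the treatment, the hours after amputation (0, 3, 6 or 24 h), the tissue and the replicate. Per the labels' protocols, the distal part of the tail was amputated, tissue was dissociated with an enzyme mix, whole cells were treated with Tn5 and the DNA was amplified by PCR with a cycle number set by qPCR. PCR copies are not independent molecules.

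Per the submitters' processing notes, the tools used upstream were Trim Galore 0.4.4, Bowtie2 2.3.4.1, Picard 2.18.5, SAMtools 1.8, MACS2 2.1.1.20160309, bedtools 2.27.1 and featureCounts 1.6.2 of the Subread package, with the genome build xenTro9. Their settings are not given in the sources used here, apart from the counting command in the file header, and neither is any shift of read ends for the Tn5 insertion. The authors deposited counts of read pairs per window for each library, made with featureCounts in paired mode from alignments whose names say that duplicates were removed, per the file headers. The windows, 247959 in number and 229 to 3074 bp wide with a median of 400 bp, were built by merging windows around the summits of all libraries, per the file headers. A window therefore exists only where some library had a summit, and counts were made over 1 common set for all libraries. The authors also deposited a summit list per library, in which each summit has a -log10 q-value from MACS2; the lowest was 1.30. Removal of duplicates before counting can cap the counts of the strongest windows in deep libraries, and windows of merged summits mix neighbouring sites.

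Counts were used as deposited. The total per library ran from 1725024 to 8354680, with a median of 3905650, and the median count per window was 11, so counting noise alone was large in most windows. Windows on the mitochondrial genome (19) stayed in the table and held 3.52% to 8.19% of the counts. Replicate pairs were checked for repeated deposits with a chi-square of their counts, and no column of the table belonged to a sample outside the labels.

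The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM normalisation, the filterByExpr filter and a Benjamini-Hochberg threshold of 0.05. TSA and DZNep were each compared with the vehicle of their own experiment and time, in a fit of all libraries of that experiment with a mean per group. Vehicle, amputated and uninjured states were compared in a fit of all 35 libraries with a term for the experiment, and also within each experiment alone. The difference between the inhibitors was tested in a fit of all 35 libraries on the 18 group means. The model, the sets, the rule for named regions and most alternatives were fixed before the data were examined. Named regions were those past the threshold in a comparison with an average log2 CPM of at least 1, in which all libraries of 1 state lay above all of the other within each experiment, up to 5 per direction by the size of the fitted log2 change. Where fewer than 10 regions passed in a comparison, all of them were named, so Peak_52281 is named although its libraries overlapped. CPM values of named regions use TMM-normalised library sizes. Sets of regions were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation. A set was drawn in the experiment that was not tested; where fewer than 50 regions passed the threshold, the 500 with the smallest p in that direction were used.

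For the comparison of opened regions between experiments, each region was matched to 10 control windows of like strength, and the mean log2 CPM (prior count 2) over regions minus that of their controls was compared between libraries by exact permutation. Summits of replicates were called shared when they lay within 100 bp.

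Alternatives were DESeq2 1.42.0 with its Wald test, median-of-ratios size factors within edgeR, no filter beyond a total of 1 count, loess offsets that depend on abundance (span 0.3), the replicate number as a block, each library left out in turn, the TSA experiment alone, and other distances and a higher score for summits. A filter at 8 CPM, that filter with loess offsets, a block with 1 library moved, a contrast that joins the 3 vehicle times and sets from all libraries after amputation were added after the data were seen. The steps were tested on simulated data with known changes in 200 windows drawn from the means and depths of these libraries.

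Whether replicate numbers pair samples was checked by correlating deviations from group means of libraries with the same number. Titles in the TSA experiment carry a run that is the same as the replicate number, and what a run was is not given in the sources used here. Correlations between groups lay between -0.03 and 0.195 for inhibitor against vehicle. With 2 libraries per group each comparison gives 1 value per experiment. For uninjured tips at 24 and 0 h the values were 0.203 in the TSA and 0.165 in the DZNep experiment, and the block changed no call there. With the run as a possible batch, the value with this block is given beside the planned comparisons whose count it moved.

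No genome or gene annotation of the build xenTro9 was used here, so regions are given by position without genes, and tests of gene lists and sequence motifs that had been planned on such an annotation were not run.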

Results

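ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, was used to follow chromatin accessibility in the tail of Xenopus tropicalis tadpoles after amputation. The 35 libraries came from 2 experiments. In the first, 18 libraries followed tails kept in trichostatin A (TSA, 20 nM), an inhibitor of histone deacetylases, or in its DMSO vehicle. In the second, 17 libraries followed tails kept in 3-deazaneplanocin (DZNep, 15 µM), used in this study to inhibit the histone methyltransferase EZH2, or in vehicle. Tissue was taken at 3, 6 and 24 h after amputation under inhibitor or vehicle, from the tissue next to the amputation plane at 0 h, and from uninjured tail tips at 0 and 24 h. Each group of an experiment held 2 libraries, except the amputated 0 h tissue of the DZNep experiment, which held 1. Comparisons that used both experiments therefore had 4 vehicle libraries per time, 4 uninjured libraries per time and 3 amputated 0 h libraries. The collected tissue differed between states, since the libraries at 3 to 24 h were of regenerated tail tissue and those at 0 h of tissue beside the plane or of whole tips.

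Counts covered 247959 windows around accessible sites, with a median width of 400 bp. Library totals ran from 1725024 to 8354680 counts in the TSA experiment and from 2464473 to 8262895 in the DZNep experiment, with a median of 3905650 over all libraries. At this depth the median count per window and library was 11. Between 13.8% and 21.1% of the counts of a library fell in the 10000 strongest windows, and between 3.52% and 8.19% in mitochondrial windows. The 17 replicate pairs differed by more than counting noise in every case (chi-square per degree of freedom 1.14 to 1.77), so none was treated as a repeated deposit of 1 library. The labels do not say whether replicates came from separate clutches or animals, so the p-values here measure only the spread between these samples, which may be technical in part. In each experiment, the TSA 24 h libraries left aside, a few windows were full in every library of 1 replicate number and empty in those of the other, so the numbers also mark a difference that libraries share. The main fits, those with 1 library left out and the exact permutation tests did not include the replicate number. Counts with it as a block are given where it moved them.

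The authors' summits, called in each library alone, numbered from 9838 to 79486 per library with a median of 22814. A median of 48.3% (SD 15.9, 34 shares from 17 replicate pairs) of the summits of a library lay within 100 bp of a summit of its replicate. Among summits with a score of at least 10 that share was 67.7% (SD 23.4). Shares of this kind move with how many summits were called, so they describe the lists and were not used to compare treatments.

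Accessibility after amputation was first compared between vehicle-treated tails and amputated tissue at 0 h, to see which sites changed during early regeneration. Peak_155734 (xenTro9 chromosome 6, 100014907 to 100015568) rose from 3.30 ± 0.515 CPM (SD, n = 3) at 0 h to 11.2 ± 2.38 CPM (n = 4) at 3 h and stood at 10.7 ± 3.59 CPM (n = 4) at 6 h. Peak_13700 (chromosome 1, 83700632 to 83701130) rose from 1.31 ± 0.364 CPM (n = 3) to 5.41 ± 1.77 CPM (n = 4) at 3 h. Peak_93331 (chromosome 4, 3205167 to 3205774) rose from 3.30 ± 1.74 CPM (n = 3) to 10.9 ± 0.716 CPM (n = 4) at 6 h. The log2 changes at 3 h were 1.74 ± 0.28 (SE) for Peak_155734 and 1.89 ± 0.35 for Peak_13700, with Benjamini-Hochberg adjusted p-values of 0.00368 and 0.0428 by edgeR's quasi-likelihood test. At 6 h they were 1.66 ± 0.29 for Peak_155734 and 1.67 ± 0.29 for Peak_93331, both with an adjusted p of 0.00969 by the same edgeR test. These were all of the regions past the threshold among 243527 windows, 2 higher and 0 lower at each time, and DESeq2 called 1 and 3. An unadjusted p under 0.05 was found in 9524 windows at 3 h (3.91%) and 11095 at 6 h (4.56%). Without any change a share of about 0.05 would have such a p. Offsets that depend on abundance gave 16 regions at 3 h and 4 at 6 h, and the replicate number as a block gave 2 and 3, all higher.

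Neither experiment alone gave a call at 3 or 6 h (0 by edgeR), with 8075 and 9393 windows at an unadjusted p under 0.05 at 3 h and 14907 and 10661 at 6 h in the TSA and the DZNep experiment. In the DZNep experiment the amputated arm is 1 library, whose spread was taken from the other groups, so its 0 rests on 1 sample in that arm. Without the amputated library of the DZNep experiment the count was 0 at both times, with log2 changes of 1.41 at Peak_155734 and 2.20 at Peak_13700 at 3 h and of 1.33 at Peak_155734 and 1.5 at Peak_93331 at 6 h. At 3 h it was 1 without either DZNep-experiment vehicle library or without TSA-experiment amputated replicate 1, and 6 without TSA-experiment vehicle replicate 1. At 6 h it was 0 without TSA-experiment amputated replicate 1 or vehicle replicate 1, 1 without DZNep-experiment vehicle replicate 1 and 5 without its replicate 2. By region, Peak_13700 fell short at 3 h in 5 of 7 fits with 1 library left out and Peak_155734 in 1. For 6 h, Peak_155734 fell short in 4 of 7 and Peak_93331 in 3.

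At 24 h in vehicle more regions passed the threshold than at 3 or 6 h, an order that depended on the scaling (below). Peak_93331 reached 12.1 ± 2.47 CPM (SD, n = 4), and Peak_144990 (xenTro9 chromosome 6, 29895111 to 29895724) rose from 3.31 ± 0.821 CPM (n = 3) to 12.1 ± 3.60 CPM (n = 4). Peak_34540 (chromosome 10, 9505295 to 9505769) rose from 2.54 ± 0.828 to 7.32 ± 1.14 CPM, and Peak_64006 (chromosome 2, 140135738 to 140136216) from 2.37 ± 1.22 to 7.57 ± 2.80 CPM. Peak_17724 (chromosome 1, 109019888 to 109020317) rose from 1.05 ± 0.469 to 4.63 ± 1.63 CPM. In edgeR's quasi-likelihood test Peak_93331 and Peak_144990 changed by 1.81 ± 0.29 and 1.8 ± 0.29 log2 units (SE), both with a Benjamini-Hochberg adjusted p of 0.000912, and the adjusted p of Peak_17724 was 0.0428. In total 22 regions were higher and 0 lower than at 0 h, with log2 changes of 1.25 to 1.99 and a median fold change of 2.99. DESeq2 called 34. With the replicate number as a block edgeR called 35, of which 33 were higher and 2 lower.

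Neither experiment alone gave a call at 24 h (0 by edgeR), with 12493 windows in the TSA and 11402 in the DZNep experiment at an unadjusted p under 0.05; the DZNep experiment again has 1 amputated library. Without the DZNep-experiment amputated library 2 regions passed, and the 5 named ones fell short with log2 changes from 1.40 at Peak_34540 to 2.35 at Peak_17724. The count was 2 and 4 without TSA-experiment amputated replicates 1 and 2, 3 and 36 without DZNep-experiment vehicle replicates 1 and 2, and 7 without TSA-experiment vehicle replicate 1. By region, Peak_17724 fell short in 6 of 7 fits with 1 library left out and Peak_64006 in 5. Peak_34540 fell short in 3, and Peak_93331 and Peak_144990 in 2 each. Offsets that depend on abundance gave 11 regions, 10 higher and 1 lower, fewer than the 16 they gave at 3 h.

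**Figure D1:**
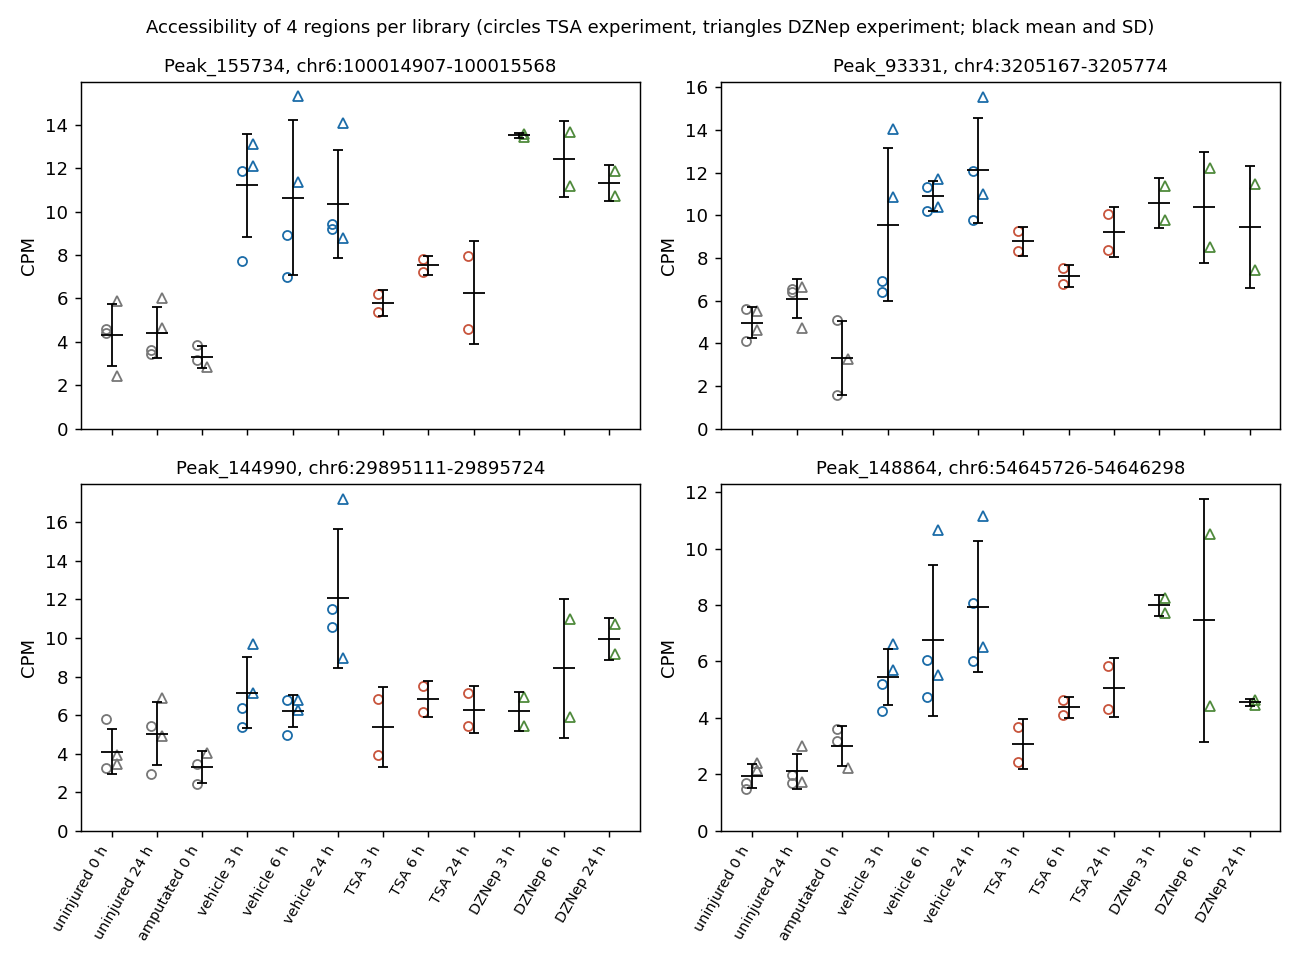
Accessibility in CPM (y axis) of 4 regions, Peak_155734, Peak_93331, Peak_144990 and Peak_148864, in each state (x axis); circles are libraries of the TSA experiment, triangles of the DZNep experiment, and black bars the mean with its SD. In vehicle, Peak_155734 stood at 11.2 CPM at 3 h against 3.30 CPM in amputated tissue at 0 h, and Peak_144990 at 12.1 CPM at 24 h against 3.31 CPM.

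Vehicle-treated tails at 24 h were also compared with uninjured tail tips at 24 h. Peak_148864 (xenTro9 chromosome 6, 54645726 to 54646298) held 7.94 ± 2.31 CPM (SD, n = 4) in regenerating tissue and 2.1 ± 0.616 CPM (n = 4) in uninjured tips. Peak_14304 (chromosome 1, 87106740 to 87107253) held 9.54 ± 2.37 against 2.84 ± 0.318 CPM, and Peak_173449 (chromosome 7, 69247632 to 69248200) 6.88 ± 1.59 against 1.67 ± 0.931 CPM. Peak_97246 (chromosome 4, 25199007 to 25199465) held 4.85 ± 2.44 against 1.37 ± 0.874 CPM, with 1 of its vehicle libraries at 8.49 CPM and the others at 3.45 to 3.77 CPM. Peak_201991 (chromosome 9, 5556134 to 5556607) held 5.25 ± 1.89 against 1.34 ± 1.27 CPM. By edgeR's quasi-likelihood test the log2 differences were 1.96 ± 0.31 (SE) for Peak_148864 and 1.66 ± 0.27 for Peak_14304, with Benjamini-Hochberg adjusted p-values of 0.00143 and 0.00154, and the adjusted p of Peak_97246 was 0.0481. In total 16 regions were higher and 0 lower, with a median fold of 2.92, and DESeq2 called 47. With the replicate number as a block edgeR called 61, of which 56 were higher and 5 lower. Of the 16 regions 2 were also among the 22 called against amputated tissue. The 5 regions named there did not pass the threshold against uninjured tips at 24 h, with log2 differences of 0.94 at Peak_93331 (adjusted p = 0.258), 0.83 at Peak_17724 (adjusted p = 0.578), 1.19 at Peak_144990 (adjusted p = 0.0640), 1.19 at Peak_64006 (adjusted p = 0.195) and 1.17 at Peak_34540 (adjusted p = 0.153) by the same edgeR test. Conversely, the 5 regions named against uninjured tips did not pass the threshold at 24 h against amputated 0 h tissue. Their log2 differences ran from 0.53 at Peak_201991 (adjusted p = 0.795) to 1.43 at Peak_148864 (adjusted p = 0.0588) by the same edgeR test. Whether the 2 comparisons differ at any of these regions was not tested.

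Neither experiment alone gave a call here (0 by edgeR), with 11307 windows in the TSA and 12759 in the DZNep experiment at an unadjusted p under 0.05. Without DZNep-experiment uninjured 24 h replicate 1 the count was 0, and the 5 named regions fell short with log2 differences from 1.51 at Peak_201991 to 1.85 at Peak_148864. Among uninjured libraries the count was 5 without DZNep-experiment replicate 2 and 3 without TSA-experiment replicate 2. Among vehicle libraries it was 1 and 55 without DZNep-experiment replicates 1 and 2, and 4 and 5 without TSA-experiment replicates 1 and 2. By region, Peak_97246 and Peak_201991 each fell short in 7 of 8 fits with 1 library left out. Peak_173449 fell short in 6, Peak_148864 in 2 and Peak_14304 in 1. Offsets that depend on abundance gave 3 regions.

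In uninjured tips Peak_155734 held 4.33 ± 1.43 CPM (SD, n = 4) at 0 h and 4.43 ± 1.18 CPM (n = 4) at 24 h, and Peak_148864 held 1.93 ± 0.426 and 2.1 ± 0.616 CPM. Other named regions lay further apart between these times. Peak_17724 held 1.46 ± 1.05 CPM at 0 h and 2.73 ± 2.34 CPM at 24 h, Peak_13700 1.58 ± 0.615 and 2.58 ± 0.437 CPM, Peak_173449 3.07 ± 1.31 and 1.67 ± 0.931 CPM, Peak_201991 2.45 ± 1.23 and 1.34 ± 1.27 CPM and Peak_97246 2.20 ± 0.485 and 1.37 ± 0.874 CPM. None of these differences passed the threshold. Between uninjured tips at 24 and 0 h edgeR's quasi-likelihood test called 0 of 243527 windows, with 13576 (5.57%) at an unadjusted p under 0.05 and 0 by DESeq2. Tissue next to the amputation plane at 0 h, compared with uninjured tips at 0 h to see the state at the start, held 3.30 ± 0.515 CPM (n = 3) at Peak_155734 and 3.00 ± 0.721 CPM at Peak_148864. There too edgeR called 0 windows, with 17086 (7.02%) at an unadjusted p under 0.05 and 0 by DESeq2. Within each experiment alone edgeR called 0 windows in both comparisons, with 8666 and 13853 at an unadjusted p under 0.05 between the uninjured times and 11871 and 13528 between amputated and uninjured tissue (TSA and DZNep experiment, the latter with 1 amputated library).

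TSA was compared with vehicle at each time to see how accessibility during regeneration differs under this inhibitor of histone deacetylases. These libraries do not measure deacetylase activity itself. At Peak_155734 the 2 libraries under TSA held 5.80 ± 0.609 CPM (SD) at 3 h, 7.52 ± 0.417 CPM at 6 h and 6.27 ± 2.36 CPM at 24 h, and the log2 differences from vehicle were -0.72 ± 0.33 (SE), -0.07 ± 0.32 and -0.58 ± 0.36. At the same times they were -0.27 ± 0.37, 0.20 ± 0.34 and -0.81 ± 0.35 at Peak_144990, -0.56 ± 0.39, -0.31 ± 0.36 and -0.44 ± 0.38 at Peak_148864, and 0.90 ± 0.35, 0.50 ± 0.36 and -0.17 ± 0.43 at Peak_13700. None of these differences passed the threshold, and in no window did TSA differ from vehicle past it. The regions shown here were named because vehicle libraries were high at them, and those libraries are also the controls for TSA. That choice alone tends to place TSA below vehicle at the times used for naming, so a negative difference there does not show an effect. By edgeR's quasi-likelihood test 0 of 233818 windows passed at 3, 6 and 24 h, and 0 by DESeq2 at each time. An unadjusted p under 0.05 was found in 9875, 8454 and 10700 windows. These were 4.22%, 3.62% and 4.58% of the windows, below the share of 0.05 that arises without any effect. The change in the TSA effect from 3 to 24 h gave 0 windows, with 9084 at an unadjusted p under 0.05 and 0 by DESeq2, and 1 without TSA 24 h replicate 1 or without vehicle 3 h replicate 2. With the replicate number as a block it gave 3, all lower.

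The titles of the TSA experiment give each library a run that is the same as its replicate number. With that number as a block, edgeR called 8 windows at 24 h, 2 higher and 6 lower under TSA, and 0 at 3 and 6 h; with the library labelled TSA 24 h replicate 2 placed in the block of replicate 1, an alternative added after the data were seen, the count at 24 h was 0. The count at 24 h without a block was 1 without TSA 24 h replicate 1 and 1 without the library labelled TSA 24 h replicate 2. In data simulated on this comparison, edgeR recovered 17 of 25 windows of at least 8 CPM changed by 4-fold, 8 of 25 changed by 3-fold and 0 of 25 changed by 2-fold. Among windows of 2 to 8 CPM it recovered 12, 2 and 0 of 25.

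The library labelled TSA 24 h replicate 2 stood apart from the other libraries of its replicate. Without the TSA 24 h libraries, 24 windows had at least 5 counts in every library of 1 replicate and at most 1 count in every library of the other, 18 of them full in replicate 1 and 6 full in replicate 2. In 100 random divisions of the same 16 libraries no window behaved in this way (0). TSA 24 h replicate 1, which like replicate 2 had no part in the choice of windows, had the replicate 1 state at 100% of them. In the DZNep experiment 24 windows, 5 full in replicate 1 and 19 in replicate 2, told all 17 libraries apart by number in the same way, against 0 in 100 random divisions. The library labelled TSA 24 h replicate 2 had full counts at 14 of the 18 windows full in replicate 1 and at 4 of the 6 full in replicate 2. It had the replicate 1 state at 66.7% and the replicate 2 state at 20.8% of the 24 windows. Values given here for TSA at 24 h include this library unless it is named as left out.

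**Figure D2:**
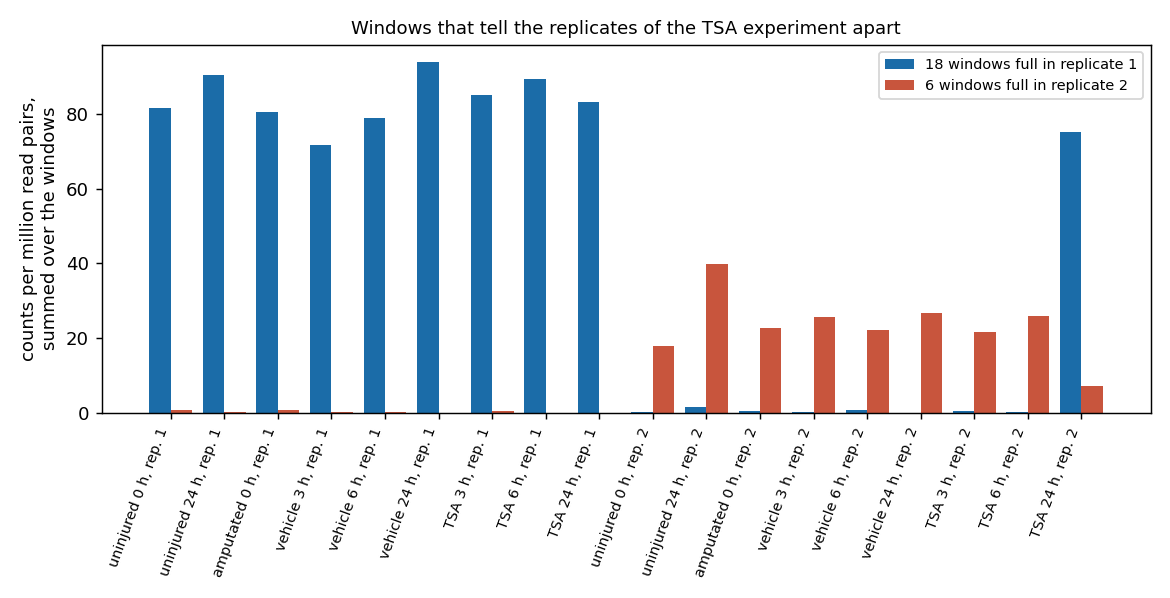
Counts in CPM (y axis) summed over the 18 windows full in replicate 1 (blue) and the 6 windows full in replicate 2 (red), in each library of the TSA experiment (x axis, ordered by replicate and state). The library labelled TSA 24 h replicate 2, at the right end, has counts in both sets of windows, with full counts at 14 of the 18 and 4 of the 6.

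DZNep, used in this study to inhibit EZH2, was compared with vehicle at each time to see how accessibility differs under it. These libraries do not measure EZH2 activity itself. At Peak_155734 the 2 libraries under DZNep held 13.5 ± 0.117 CPM (SD) at 3 h, 12.4 ± 1.77 CPM at 6 h and 11.3 ± 0.817 CPM at 24 h, with log2 differences from vehicle of 0.10 ± 0.33 (SE), -0.11 ± 0.34 and 0.00 ± 0.34. At the same times the differences were 0.39 ± 0.37, -0.11 ± 0.36 and -0.94 ± 0.37 at Peak_148864, and -0.50 ± 0.37, 0.38 ± 0.38 and -0.38 ± 0.33 at Peak_144990. As with TSA, vehicle libraries that served to name these regions are also the controls, which alone tends to lower the differences. None of the differences at these regions passed the threshold. Only Peak_52281 (xenTro9 chromosome 2, 64153061 to 64153460) and Peak_52282 (chromosome 2, 64154050 to 64154449) did, both at 6 h. Their log2 differences were 5.25 ± 0.82 and 5.99 ± 0.78, with Benjamini-Hochberg adjusted p-values of 0.000607 and 4.18e-06 by edgeR's quasi-likelihood test.

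Both calls came from 1 library. DZNep 6 h replicate 2 held 23.2 CPM at Peak_52281 and 38.6 CPM at Peak_52282, against 0.294 and 0.882 CPM in replicate 1, so the means of 11.7 ± 16.2 and 19.7 ± 26.7 CPM (SD) describe neither library. In vehicle at 6 h the regions held 0.290 ± 0.0241 and 0.308 ± 0.435 CPM. In total 2 windows were higher and 0 lower at 6 h among 234271, with 10061 (4.29%) at an unadjusted p under 0.05 and 0 by DESeq2. Without DZNep 6 h replicate 2, or without vehicle 6 h replicate 1, 0 windows passed at 6 h, without DZNep 6 h replicate 1 5 passed and without vehicle 6 h replicate 2 1 passed. At 3 and 24 h edgeR called 0 windows, with 8010 (3.42%) and 9790 (4.18%) at an unadjusted p under 0.05 and 0 by DESeq2. The count at 3 h was 1 without vehicle 3 h replicate 1 and 1 with the replicate number as a block, which gave 3 at 6 h. The change in the DZNep effect from 3 to 24 h also gave 0, with 7666 at an unadjusted p under 0.05 and 0 by DESeq2.

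The effects of the inhibitors were compared with each other as differences from their own vehicles. In no window did the TSA effect differ from the DZNep effect past the threshold. By edgeR's quasi-likelihood test 0 of 243527 windows passed at 3, 6 and 24 h, and 0 by DESeq2 at each time. An unadjusted p under 0.05 was found in 9246, 10180 and 11447 windows (3.80%, 4.18% and 4.70%). Across 14512 windows of at least 8 CPM the log2 changes under TSA and under DZNep had correlations of 0.0765 at 3 h, 0.0615 at 6 h and -0.0604 at 24 h. These correlations are across windows, which are not independent replicates.

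Groups of regions that opened or closed after amputation were then followed under each inhibitor. Each set was chosen in the other experiment, so that a set and its test shared no library. In neither experiment alone did a region pass the threshold between vehicle and amputated 0 h tissue (0 for each set), so each set took the 500 regions with the smallest p in its direction. The opened sets were also read in vehicle against amputated tissue of the tested experiment. In the TSA experiment they differed from other regions by 0.12, 0.04 and 0.27 log2 units at 3, 6 and 24 h. In the DZNep experiment, with 1 amputated library, the values were 0.18, -0.05 and 0.30. Regions opened by 6 h in the TSA experiment were thus, as a set, not higher at 6 h in the DZNep experiment. Regions opened by 6 h stood higher under DZNep than vehicle at 6 h, by 0.17 log2 units over other regions, and regions opened by 24 h stood lower under DZNep at 24 h, by -0.16. Both had a Benjamini-Hochberg adjusted p of 0.000929 over 12 camera tests with a preset correlation of 0.01, and an adjusted p of 0.970 with an estimated correlation, so neither call held there. The difference at 6 h was -0.0420 without DZNep 6 h replicate 2 and 0.0402 without vehicle 6 h replicate 2, and the difference at 24 h was -0.10 without DZNep 24 h replicate 1 and -0.00289 without vehicle 24 h replicate 1. Of all 35 libraries, vehicle 24 h replicate 1 had the highest share of counts in strong windows (21.1%) and the most summits with a score of at least 10 (19055), and vehicle 6 h replicate 2 had the lowest such share (13.8%). Mitochondrial windows held 7.24 ± 1.18% (SD, n = 2) of the counts under DZNep at 24 h and 4.61 ± 0.88% (n = 2) in vehicle. With abundance-dependent offsets the set differences under DZNep at 6 and 24 h were 0.0665 and -0.10. In the TSA experiment regions opened by 3, 6 and 24 h differed from other regions under TSA by -0.01, 0.01 and -0.06 log2 units, each with an adjusted p of 0.990 by camera. The sets of closed regions gave no call under either inhibitor. Read in vehicle against amputated tissue, closed sets of 3, 6 and 24 h differed by 0.005, 0.13 and -0.16 log2 units in the TSA experiment. In the DZNep experiment the values were -0.02, 0.06 and -0.09. At 3 and 6 h these sets thus did not clearly close in the tested experiment, so the lack of a call there says little about closing regions.

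Because the planned sets held no region past the threshold, wider sets were added after the data were seen. They compared all libraries at 3 to 24 h after amputation, under vehicle or inhibitor, with the uninjured and amputated 0 h libraries of 1 experiment, and were read in the other experiment against control windows of matched strength. The number of regions called for these sets moved with the setting in both experiments (below). In the TSA experiment the 360 regions opened in the DZNep experiment stood 0.42 log2 units higher in the 12 libraries at 3 to 24 h (0.11 ± 0.08, SD) than in the other 6 libraries (-0.31 ± 0.12), and all 12 lay above all 6 (exact permutation test, two-sided, p = 5.39e-05, Benjamini-Hochberg adjusted p = 0.000646 over 12 tests). In the DZNep experiment the 175 regions opened in the TSA experiment stood 0.49 log2 units higher in the 12 libraries at 3 to 24 h (0.13 ± 0.11) than in the other 5 (-0.36 ± 0.05), and again all 12 lay above the others (exact permutation test, p = 0.000162, adjusted p = 0.000970). Over uninjured tips at 0 h, opened regions stood 1.45-fold, 1.37-fold and 1.40-fold higher in vehicle at 3, 6 and 24 h of the TSA experiment and 1.35-fold, 1.41-fold and 1.37-fold higher under TSA. In the DZNep experiment the folds were 1.51, 1.40 and 1.44 in vehicle and 1.51, 1.47 and 1.35 under DZNep. Uninjured tips at 24 h stood at 0.995-fold and 1.06-fold.

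Averaged over the 3 times, neither inhibitor changed these opened regions by more than the spread between libraries. The difference between TSA and vehicle, with labels exchanged only within times, was -0.03 log2 units (n = 6 and 6, exact permutation test, p = 0.546, adjusted p = 0.630). Between DZNep and vehicle it was -0.01 (n = 6 and 6, exact permutation test, p = 0.907). Against other regions the 175 stood -0.04 log2 units under DZNep at 3 h, 0.25 at 6 h and -0.21 at 24 h, with adjusted p-values of 0.752, 5.81e-06 and 5.41e-05 over 12 camera tests at a preset correlation of 0.01 and of 0.918 for each with an estimated correlation, so neither call held there. Under TSA the 360 stood at -0.04, 0.03 and -0.05 (adjusted p = 0.384, 0.704 and 0.752 by camera). A p that misses the threshold does not show that the inhibitors left these regions as they were.

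**Figure D3:**
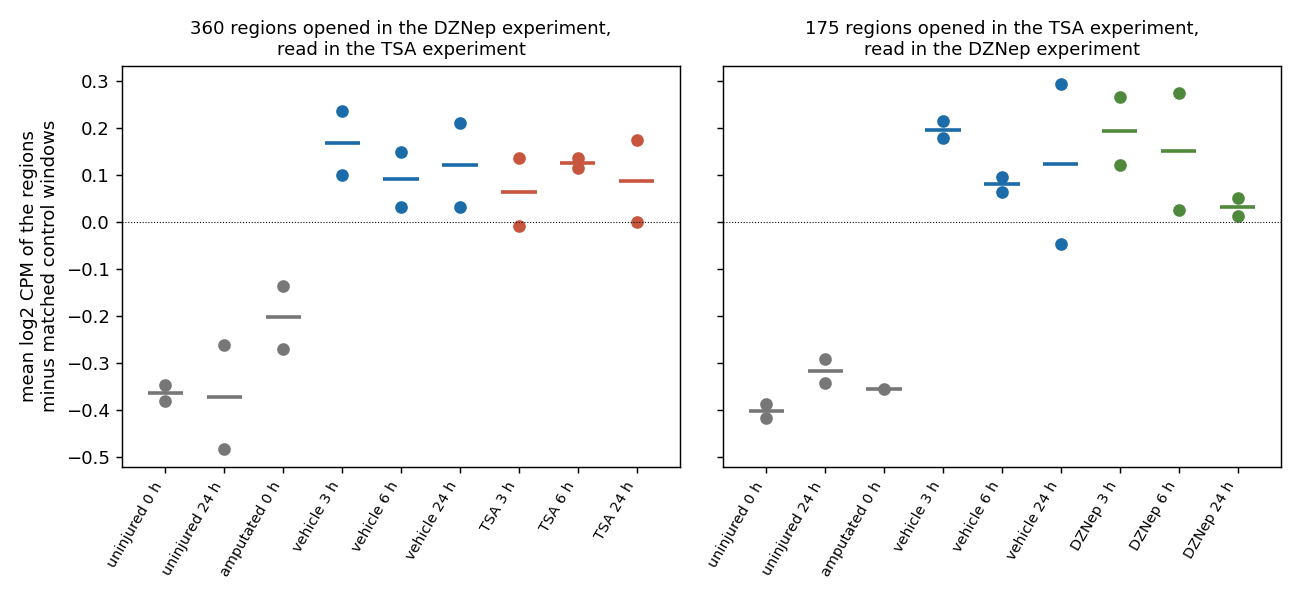
Mean log2 CPM of opened regions minus that of matched control windows (y axis) in each library, by state (x axis); the left panel reads 360 regions in the TSA experiment and the right panel 175 regions in the DZNep experiment, with points for libraries and lines for means. In both panels the 12 libraries at 3 to 24 h after amputation lie above the uninjured and amputated 0 h libraries, by 0.42 and 0.49 log2 units on average.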

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

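The tests of the library labelled TSA 24 h replicate 2 for a wrong label, a swap and a mixture, and of its counts at windows full in replicate 2, were chosen after its counts were seen; the test for 1 mixing proportion at windows full in replicate 1 and both tests of the DZNep sets were fixed before their results were seen, except that setting their overlap against an SD came after.

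At the 24 windows that tell the replicates of the TSA experiment apart, the library labelled TSA 24 h replicate 2 had the replicate 1 state at 66.7% and the replicate 2 state at 20.8%. Each other library, read at windows chosen without it, had its own replicate's state at 77.4% to 100% and the other state at no more than 9.68%. A swap of the TSA 24 h libraries is excluded, since TSA 24 h replicate 1 had the replicate 2 state at 0 windows. A replicate 1 library with a wrong label would have its own state in about that range, yet the library had counts at 66.7% of the windows full in replicate 2, which a mixture of material from both replicates may explain. Its counts over the windows full in replicate 1 had a chi-square per degree of freedom of 1.90, within the 0.738 to 2.93 of the replicate 1 libraries. Over the 6 windows full in replicate 2, where it had 0 counts at 2 windows and 5 to 8 at the others, the value was 6.41, against 0.589 to 6.35 in the other replicate 2 libraries at windows chosen without them. That is higher than all of them but by less than their SD (1.81), so a single mixing proportion stays open. A separate batch of parents that carries some of each replicate's alleles also stays open and was not tested.

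Regions opened by 6 h stood higher and regions opened by 24 h lower under DZNep, and both calls were lost with an estimated correlation (adjusted p = 0.970 by camera for each). The set opened by 6 h, drawn in the TSA experiment, was not higher at 6 h in vehicle of the DZNep experiment (-0.05 log2 units over other regions). Opposite effects of DZNep at the 2 times would put the DZNep libraries outside the range of the vehicle libraries at both times. Over matched controls the DZNep libraries at 6 h (-0.0334 to 0.110) overlapped those of vehicle (-0.0371 to 0.0346), with a gap of -0.0681. At 24 h both DZNep libraries (0.00041 to 0.0213) lay below both vehicle libraries (0.0509 to 0.162). By the rule set in advance, the overlap at 6 h goes against opposite effects. It is smaller than the SD of the 2 DZNep libraries at 6 h (0.102), a bound added later. With 2 libraries per group that bound cannot decide the question. Offsets that depend on abundance left a share of 0.380 of the set difference at 6 h, under the bound of 0.5 set in advance for both, and of 0.639 at 24 h, above it, which does not decide whether the share of counts in strong windows contributes to them. The call at 6 h was lost without DZNep 6 h replicate 2 (-0.0420) and without vehicle 6 h replicate 2 (0.0402), and that at 24 h without vehicle 24 h replicate 1 (-0.00289) and without DZNep 24 h replicate 1 (-0.10).

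In groups of 4 libraries a few single values lay far from the other 3. Of 100 groups tested, 9 held such a value, where chance gives about 5. At Peak_97246, uninjured 0 h replicate 2 of the TSA experiment had 1.47 CPM where the others had 2.41 to 2.50, and vehicle 24 h replicate 1 of the DZNep experiment had 8.49 where the others had 3.45 to 3.77. At Peak_52282, vehicle 3 h replicate 2 of the DZNep experiment had 3.03 CPM where the others had 0.168 to 0.448, and vehicle 24 h replicate 2 had 0.612 where the others had 0. At Peak_62265, vehicle 6 h replicate 2 of the DZNep experiment had 7.38 CPM where the others had 10.1 to 10.5. The same library had 13.8% of its counts in strong windows where the others had 18.0% to 18.4%. At Peak_155734, vehicle 24 h replicate 1 of the DZNep experiment had 14.1 CPM where the others had 8.77 to 9.42. At Peak_93331, uninjured 24 h replicate 2 of the DZNep experiment had 4.73 CPM where the others had 6.39 to 6.65. Uninjured 24 h replicate 1 of the TSA experiment had 71536 summits where the others had 14414 to 21311.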

How the results depend on the processing

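The filter at 8 CPM, its combination with loess offsets, the moved block, the contrast over all vehicle times and the sets within each experiment were tests chosen after the data were seen; the other alternatives were planned. Of 209 values of the main results under an alternative setting, 166 were kept and 43 changed. A count was kept within 1.5 times of the main count, or where both were 0, and a share of summits within its SD. A set difference was kept if it stayed on the same side of the threshold, and past it also in its direction. Direction was not checked for counts or for sets short of the threshold. The set opened by 24 h under TSA ran from -0.16 to 0.03 with 1 library left out and was still kept. Of 179 values with 1 library left out, 141 were kept and 38 changed. For the 21 pairs of a named region and a comparison, 272 of 356 values stayed past the threshold, 84 fell short of it in the same direction and 0 reversed; 16 of the pairs fell short without some single library. Planned tests of gene lists and motifs were not run, since no annotation or genome of the build xenTro9 was used here. The causes of the changes listed here were not tested, except that a filter or a single experiment tests fewer windows or libraries. In data simulated at the depths and library numbers of these comparisons, edgeR recovered 0 of 25 2-fold changes for TSA at 24 h (2 against 2 libraries) and 11 of 25 for vehicle at 24 h against amputated tissue (4 against 3), in windows of at least 8 CPM; in windows of 2 to 8 CPM it recovered 0 and 3 of 25.

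DESeq2 called 34 regions for vehicle at 24 h against amputated 0 h (edgeR 22), 47 for vehicle against uninjured tips at 24 h (edgeR 16), 1 for vehicle at 3 h (edgeR 2) and 0 for DZNep at 6 h (edgeR 2). For all libraries at 3 to 24 h against the others, it called 62 in the TSA experiment (edgeR 181) and 82 in the DZNep experiment (edgeR 380).

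Windows of at least 8 CPM gave 9 regions at 3 h and 5 at 6 h for vehicle against amputated tissue, 0 for DZNep at 6 h and 218 for vehicle at 3 to 24 h against uninjured and amputated tissue (751 without the filter). For all libraries within an experiment they gave 684 in the TSA and 111 in the DZNep experiment. With no filter, DZNep at 3 h gave 1.

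Loess offsets gave 16, 4 and 11 regions for vehicle at 3, 6 and 24 h against amputated tissue, 3 against uninjured tips at 24 h, 1 for TSA at 24 h, 1 for its change from 3 to 24 h and 41 for all libraries of the TSA experiment. Sets opened by 6 and 24 h then differed under DZNep by 0.0665 (adjusted p = 0.594 by camera) and -0.10 (adjusted p = 0.0682 by camera). Offsets together with the 8 CPM filter gave 30, 5 and 11 regions for vehicle at 3, 6 and 24 h, 3 against uninjured tips at 24 h, 3 for amputated against uninjured tissue at 0 h, 0 for DZNep at 6 h, 23 for all libraries of the TSA experiment and 278 for vehicle at 3 to 24 h, of which 226 were higher and 52 lower (716 and 35 in the unmodified fit).

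With the replicate number as a block, edgeR called 8 regions for TSA at 24 h, 3 for its change from 3 to 24 h, 1 for DZNep at 3 h, 35 for vehicle at 24 h against amputated tissue (33 higher, 2 lower), 61 against uninjured tips at 24 h (56 higher, 5 lower) and 780 for all libraries of the TSA experiment. It moved vehicle at 6 h and DZNep at 6 h from 2 to 3 each, all libraries of the DZNep experiment from 380 to 523 (474 higher, 49 lower) and vehicle at 3 to 24 h from 751 to 1054 (964 higher, 90 lower). What the numbers of the DZNep experiment mark is not given in the labels; correlations between DZNep and vehicle were 0.109 to 0.120, and 24 windows tell its libraries apart by number. With the library labelled TSA 24 h replicate 2 moved to the block of replicate 1, TSA at 24 h gave 0 and all libraries of the TSA experiment gave 510.

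In the TSA experiment alone, vehicle gave 0, 0 and 0 regions at 3, 6 and 24 h against amputated tissue, 0 against uninjured tips at 24 h and 19 at 3 to 24 h against all of these.

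Over the replicate pairs of both experiments, shared summits rose to 67.7% at a score of at least 10.

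With 1 library left out, the lone library of a group was assumed to vary like the other groups. The counts then ranged from 0 to 6 for vehicle at 3 h, 0 to 5 at 6 h and 2 to 36 at 24 h against amputated tissue, and from 0 to 55 against uninjured tips at 24 h. They ranged from 0 to 1 for TSA at 24 h, 0 to 1 for its change from 3 to 24 h, 0 to 1 for DZNep at 3 h and 0 to 5 for DZNep at 6 h. The contrast of vehicle at 3 to 24 h ranged from 318 (without the DZNep-experiment amputated library) to 972, with 420 without DZNep-experiment vehicle 24 h replicate 1. The set opened by 24 h ranged from -0.33 to -0.00289 under DZNep, the low end without vehicle 24 h replicate 2 and the high end without its replicate 1. The set opened by 6 h ranged from -0.0420 to 0.38 and reversed to -0.0420 without DZNep 6 h replicate 2.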

Other observations

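The contrast that joins all vehicle times, its reading in the other experiment and the test of neighbouring regions were tests chosen after the planned comparisons had been seen, and so were the reading of a batch and the splits of libraries within experiments and within replicate numbers.

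Joined over 3, 6 and 24 h, vehicle-treated tails differed from uninjured and amputated 0 h tissue at many more regions than at any single time. The counts are not like for like, since the joined contrast has more libraries per group and uninjured tips beside amputated tissue as reference. In simulated windows of at least 8 CPM it recovered 25 of 25 2-fold changes, against 11 of 25 for vehicle at 24 h against amputated tissue. Peak_155734 held 10.7 ± 2.62 CPM (SD, n = 12) after amputation and 4.08 ± 1.16 CPM (n = 11) in the other states, and Peak_148864 6.71 ± 2.19 against 2.28 ± 0.699 CPM. Peak_62265 (xenTro9 chromosome 2, 130459416 to 130460102) held 10.8 ± 1.68 against 4.59 ± 1.07 CPM, and Peak_12390 (chromosome 1, 75717124 to 75717785) 8.79 ± 3.32 against 3.50 ± 1.65 CPM. Peak_13700 held 4.56 ± 1.26 against 1.87 ± 0.726 CPM. Their log2 differences were 1.40 ± 0.16 (SE), 1.55 ± 0.18, 1.21 ± 0.15, 1.28 ± 0.16 and 1.31 ± 0.20, with Benjamini-Hochberg adjusted p-values of 1.94e-09, 3.87e-09, 1.00e-07, 1.27e-07 and 1.90e-05 by edgeR's quasi-likelihood test. In the TSA experiment alone Peak_13700 and Peak_12390 fell short (adjusted p = 0.111 and 0.0840 by edgeR). In all, 716 regions were higher and 35 lower, with a median fold of 1.71 for the higher ones. That balance moved to 226 higher and 52 lower with offsets and the 8 CPM filter and to 964 and 90 with the replicate number as a block, and DESeq2 called 581 higher and 18 lower. In the same contrast edgeR called 19 regions in the TSA experiment alone (18 higher, 1 lower) and 168 in the DZNep experiment alone (162 higher, 6 lower). The count over both experiments was 318 without the DZNep-experiment amputated library and 420 without DZNep-experiment vehicle 24 h replicate 1.

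Regions that opened after amputation in 1 experiment were also more accessible after amputation in the other. Among 227275 windows tested in both, with all libraries at 3 to 24 h, 175 regions opened in the TSA experiment and 360 in the DZNep experiment, and 32 were in both lists. The counts behind the lists moved with the setting in both experiments, as given above. Regions of the TSA list changed by 0.51 log2 units in the DZNep experiment, 86.9% of them in the same direction, and regions of the DZNep list by 0.485 in the TSA experiment, 92.8% in the same direction. Closed regions, 6 and 16 in number, changed by -0.21 log2 units in the DZNep experiment (83.3% in the same direction) and by -0.05 in the TSA experiment (50%). Over all 14512 windows of at least 8 CPM the changes of the 2 experiments agreed at most weakly, with a correlation of 0.251 for this comparison and of 0.147, -0.0353 and 0.163 for vehicle at 3, 6 and 24 h against amputated 0 h; windows are not independent replicates.

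Opened regions may mark a response to amputation common to both experiments, which is a hypothesis. A batch of 1 experiment is excluded as the whole cause by the 0.485 log2 units in the other experiment, and a difference in the share of counts in strong windows by the 0.42 log2 units over matched controls. That share was 17.3% after amputation and 15.4% in the other libraries of the TSA experiment (exact permutation test, p = 0.0379, adjusted p = 0.454 over 12 tests), and the count of that experiment moved from 181 to 41 with loess offsets. In the DZNep experiment it was 17.1% after amputation and 18.5% in the others (exact permutation test, p = 0.180, adjusted p = 0.954), the other way. Exposure to vehicle cannot be told apart from amputation, since 0 libraries were of uninjured tails kept in vehicle. The tissue collected also differs between the states, and a difference in cell types was not tested.

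Opened regions had more close neighbours than random windows of like strength. Among the 716 there were 138 pairs of neighbours within 100 kb, against a median of 47 and a highest value of 70 in 1000 random lists of windows of like strength (permutation test, p = 0.001, the smallest these lists can give). A random draw of windows matched on strength is therefore an unlikely source of this many pairs. Windows of the common set can overlap or lie side by side, and the random lists were matched on strength. Some pairs may be windows of the same site, so the test cannot tell whether separate sites lie close together. Whether these pairs share a gene or a domain was not tested, since no annotation of this build was used here.

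Other divisions, or splits, of the same libraries were tried for each comparison of at least 3 libraries per group, among windows of at least 8 CPM. Since libraries can be exchanged only within their experiment, each single comparison has 18 divisions, too few for a share under 0.05. Against amputated 0 h tissue the real division gave 9 regions at 3 h (0 the highest of the others), 5 at 6 h (2) and 28 at 24 h (16), and vehicle against uninjured tips at 24 h gave 19 (0), each reached by 1 of the 18. Among 35 divisions that also exchange libraries between experiments the highest others were 1, 2, 16 and 0. Uninjured tips at 24 against 0 h and amputated against uninjured tissue at 0 h had 0 regions in the real division (0 and 1 the highest of the others), so all 18 gave as many by necessity and say nothing about chance. For the joined contrast the real division gave 233 regions, and 2 of 100 divisions within experiments, the real one included, gave as many. The other one gave 4359, many times the real count, which points to a structure of the samples, and the next gave 61. Averaged over the experiments, its groups differed by 2.31 percentage points in the share of counts in strong windows. That was more than in any other of these divisions (1.88), and the real groups differed by 0.2. Opposite differences cancel in this average. In the real division vehicle held 17.2% against 15.4% in the TSA experiment and 17.1% against 18.5% in the DZNep experiment. The joined contrast gave 827 regions with offsets that depend on abundance (751 without). The fit of these divisions had only the group and the experiment as terms, so its count differs from the 218 of the full fit in such windows, and it left the replicate number out. With divisions within experiment and replicate number and that number as a block, the real division gave 290 regions (33 the highest of the others). With loess offsets as well it gave 371 (10). Each count was reached by 1 of 100, the smallest share these divisions can give. A chance division is thus an unlikely source of the joined contrast in windows of at least 8 CPM with that block. Weaker windows were not divided in this way.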
